A study of Mus musculus with 9 samples.

How the data were processed

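Gene expression was measured in 9 samples of splenic CD4+CD25+ regulatory T cells of C57BL/6 mice on a 1-colour Affymetrix array with perfect-match probes only. Per the labels' protocols, mice received LCMV Armstrong into the peritoneum or LCMV clone 13 into a vein, cells were isolated with a magnetic kit at day 0 or day 16, and biotin-labelled cRNA was made from total RNA. The labels call the samples biological replicates, 3 in each of the naive, acute and chronic groups. They give no batch or date, so replicate numbers were not taken as pairs.

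The deposited table held 1 intensity per probe set and array on a linear scale, all above 0. Per the submitters' processing notes the values came from MAS5 and Affymetrix Expression Console 1.3.1, without settings. MAS5 in its usual form uses mismatch probes, which this array lacks, and the trimmed means (2% to 98%) ran from 232.6 to 241.8 where a global scaling would make them equal, so the method of summarisation and scaling stayed unknown. After log2 the medians of all probe sets were 4.73, 4.60 and 4.62 on naive replicates 1 to 3, 4.62, 4.72 and 4.67 on acute replicates 1 to 3, and 4.62, 4.63 and 4.63 on chronic replicates 1 to 3, so the columns were not centred on a common median. No further normalization was applied.

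Of 45141 probe sets, 104 were controls, 28898 had 1 gene symbol, 551 had several and 15588 had none in the table of names, and only those with 1 symbol were used. Names came from the array's annotation and were matched by Entrez identifier to the RefSeq gene table of the mouse assembly GRCm38.p6, which served for names only: 28689 matched and 209 kept the symbol of the array. Each of 17097 genes was represented by its probe set with the highest mean log2 value, and 10420 genes above the 50th percentile of the array on at least 3 arrays were tested. Tigit and Ccr7 had no probe set named here and were not analysed, and some other genes of the panel are not reported here.

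The 3 comparisons (acute against naive, chronic against naive, chronic against acute) came from 1 fit over all 9 arrays with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, eBayes with trend), two-sided, with Benjamini-Hochberg adjustment over the 10420 genes and a threshold of 0.05. The groups are small, and the number of arrays limits the precision. Gene lists were written before the data were examined: 32 lists held 545 genes, of which 466 had a probe set named and 431 were tested. Lists were tested with camera at a preset correlation of 0.01, adjusted over all 96 tests. Camera with an estimated correlation and fry, which asks whether a list's genes move one way on balance, were run beside it. Array quality values were compared with two-sided exact permutation tests.

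The lists covered regulatory T cell identity, effector regulatory T cells, resting T cells, inhibitory receptors, exhaustion transcription factors, suppressive effectors, costimulatory and TNF receptors, the Th1, Th2, Th17 and follicular programmes, type I and type II interferon responses, immediate early genes, heat shock, both cell cycle phases, oxidative phosphorylation, glycolysis, cholesterol synthesis, ribosomal proteins, chemokine receptors and adhesion. They also covered markers of CD8 T cells, NK cells, B cells, plasma cells, monocytes and macrophages, dendritic cells, neutrophils, red cells and megakaryocytes, stroma and endothelium, and cytokines of conventional CD4 T cells.

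Genes were named by a rule fixed before the data were examined. It took, per comparison, the 10 largest rises and the 10 largest falls among called genes whose groups did not overlap (chance gives 10% of genes without overlap at 3 against 3 arrays), or the 5 smallest p per direction where none passed. It added up to 4 members of each list with the smallest adjusted p and a fixed panel of receptors, cytokines and transcription factors. Receptor and immunoglobulin segments and unnamed gene models were not named by the rule.

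The responses to acute and chronic infection were compared by their covariance and correlation across genes and by the genes called in both, against 100 simulations of unchanged groups that shared the naive arrays. The methods were tested on simulated data with 200 changed genes among 10420: at the size of these groups, 64%, 65% and 63% of 2-fold changes and 95%, 97% and 93% of 4-fold changes were called in acute against naive, chronic against naive and chronic against acute, and 7.56%, 4.14% and 3.70% of the calls were false. The simulated genes were independent and normal, with the same spread in all groups and no outlying array. These shares therefore do not give the power of the comparisons of the real arrays.

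Alternatives fixed beforehand were no filter or a stricter one (75th percentile), quantile normalization, equal array medians, an offset of 32, the mean of a gene's probe sets, probe sets of ambiguous type left out, eBayes without trend or robust, array weights, only the 6 arrays compared, the replicate number as a block, each array left out in turn, a fold change of at least 2, and every probe set tested. Added after the data had been seen were the B cell list mean as a covariate, the same without the array labelled naive replicate 2, and the list tests and overlap without that array. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.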

Results

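The data were array measurements of gene expression in regulatory T cells of C57BL/6 mice infected with lymphocytic choriomeningitis virus (LCMV). Regulatory T cells are CD4 T cells that restrain other immune cells, depend on the transcription factor Foxp3 and carry the interleukin 2 receptor chain CD25 (Il2ra) on their surface. The cells were CD4+CD25+ cells taken from spleens with a magnetic isolation kit. The 9 arrays fell into 3 groups of 3 biological replicates: uninfected mice (naive, day 0), mice at day 16 after the Armstrong strain, which is cleared (acute), and mice at day 16 after the clone 13 strain, which persists (chronic). Each comparison between groups covered 10420 genes, and the number of arrays limited the precision. Across the 96 tests of gene lists (32 lists, 3 comparisons) 52 passed the camera test with a preset correlation, and 0 of these passed with an estimated correlation. With fry 27 of the 96 tests passed. The 3 comparisons asked how regulatory T cells differed after a cleared infection, during a persistent one, and between both.

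One array did not carry the transcripts of its label. On the array labelled naive replicate 2, Foxp3 stood at 5.23 on the log2 intensity scale, against 10.37 to 10.95 on the other 8 arrays, 42.6-fold below their mean. Il2ra stood at 4.65 there (9.85 to 10.58 elsewhere), Ctla4, an inhibitory receptor of regulatory T cells, at 7.32 (10.80 to 12.03), Klrg1 at 6.64 (11.16 to 12.17) and Ikzf2, the regulatory T cell transcription factor Helios, at 9.53 (12.30 to 12.72). Of the 15 measured genes of the regulatory T cell identity list, 14 were lowest on this array and at least 1 log2 unit below the mean of the other 8. Cd4 and general T cell transcripts were kept: Cd4 stood at 10.15 (9.41 to 9.81 elsewhere), Cd3e at 11.18 (10.93 to 11.24) and Cd3d at 13.17 (13.00 to 13.14). Cd2 was slightly below the other arrays (12.53 against 12.63 to 13.06). This array stayed in its labelled group, and values without it are given for the numbers of called genes, the means of the lists called against naive and part of the named genes.

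**Figure D1:**
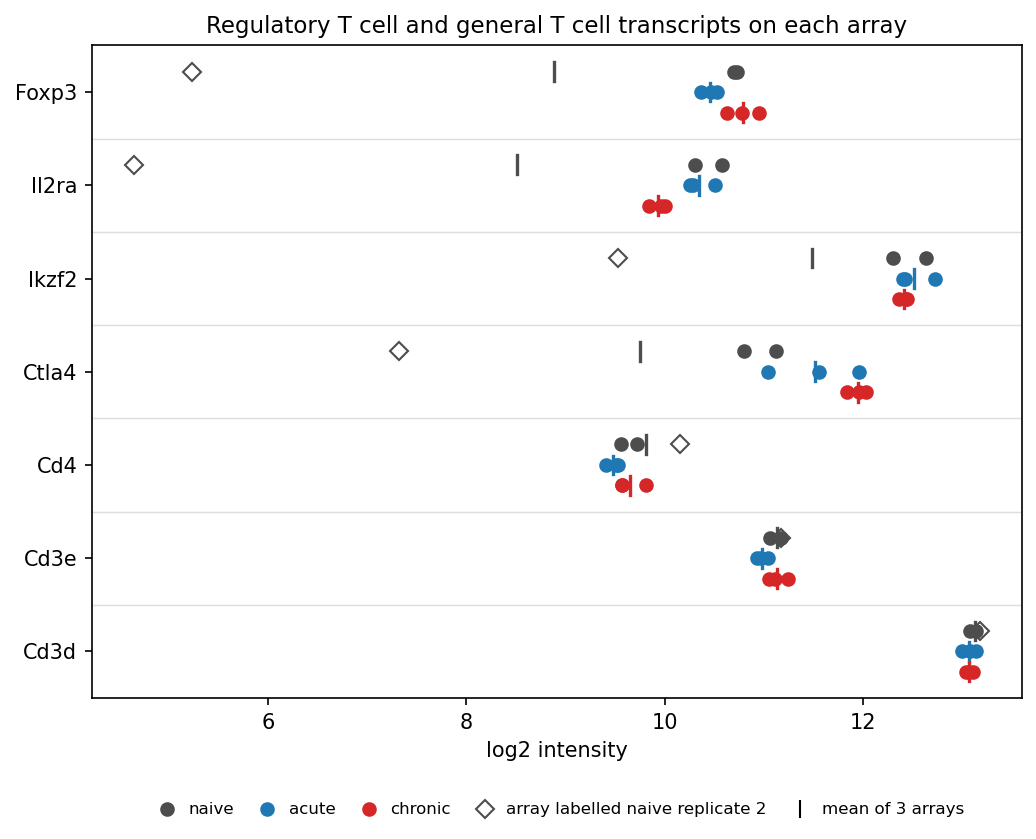
Log2 intensity (x axis) of regulatory T cell genes (Foxp3, Il2ra, Ikzf2, Ctla4), the CD4 lineage gene Cd4 and general T cell genes (Cd3e, Cd3d) on each of the 9 arrays, with a point for each array, a vertical tick for each group mean and an open diamond for the array labelled naive replicate 2. Foxp3 stood at 5.23 on that array and between 10.37 and 10.95 on the other 8, while Cd3e stood at 11.18 there and between 10.93 and 11.24 elsewhere.

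The arrays of chronic infection differed from the naive ones in effector, interferon and proliferation genes. Neutrophil and CD8 T cell list means were higher on them as well (10.09 against 7.34 and 9.28 against 8.14). Which cells a change came from was therefore not settled. The cytokine gene Il10 was 19.5-fold higher (10.20 ± 0.13 against 5.91 ± 0.95 on the log2 scale, SD, n = 3 each), and Gzmb, which encodes the cytotoxic protease granzyme B, was 13.0-fold higher (12.99 ± 0.13 against 9.29 ± 0.58). The inhibitory receptor genes Lag3, Havcr2 (TIM-3) and Pdcd1 (PD-1) rose 9.63-fold, 7.97-fold and 3.34-fold. These rises were smaller without the array labelled naive replicate 2: 13.4-fold for Il10, 10.3-fold for Gzmb, 6.04-fold for Lag3, 6.75-fold for Havcr2 and 2.23-fold for Pdcd1. Havcr2 exceeded the highest nonspecific control probe set on 1 of 3 naive arrays, so its fold is approximate. The largest falls included Sox4 (8.21-fold lower) and the transcription factor genes Bach2 and Foxp1, both of which keep lymphocytes in a resting state (4.95-fold and 4.97-fold lower). In all, 2184 genes changed at an adjusted p under 0.05 (limma), 1353 up and 831 down, and 594 and 158 of these by at least 2-fold. Without the array labelled naive replicate 2 the count was 2548 (1563 up, 985 down), which shared 1907 genes with the first. It was 1226, 1252 and 999 without chronic replicates 1, 2 and 3.

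Among called genes whose 3 arrays per group did not overlap, the 10 largest rises were Lcn2 (log2 difference 4.81 ± 0.82, SE, adjusted p = 0.00495), Slpi (4.39 ± 0.31), Il10 (4.28 ± 0.48), Sostdc1 (4.17 ± 0.32), Slfn4 (4.17 ± 0.45), Ltf (4.10 ± 0.68), Gzmk (4.07 ± 0.45), Camp (4.03 ± 0.87), Chil4 (3.99 ± 0.76) and Il1r2 (3.97 ± 0.76). Lcn2, Ltf and Camp encode neutrophil granule proteins and stood on the neutrophil list fixed beforehand. Chil4, which was not on that list, ranked the arrays of each group in the same order as Lcn2. The 10 largest falls were Tdrp (-3.23 ± 0.74), Sox4 (-3.04 ± 0.28), Tmem108 (-2.87 ± 0.38), Cnn3 (-2.76 ± 0.43), Igfbp4 (-2.46 ± 0.58), St8sia6 (-2.44 ± 0.16), Tgfbr3 (-2.37 ± 0.60), Foxp1 (-2.31 ± 0.32), Bach2 (-2.31 ± 0.32) and Il6ra (-2.30 ± 0.35). Adjusted p-values of these 20 genes ran up to 0.0237, for Tgfbr3. Sizes and order depended on the array labelled naive replicate 2. Without it Lcn2 differed by 3.81, Ltf by 3.29, Chil4 by 3.02, Camp by 2.93, Il1r2 by 2.88, Tdrp by -2.16, Igfbp4 by -1.62 and Tgfbr3 by -1.51, and Gzmk (4.45) and Sox4 (-2.88) differed most among the 20. On naive arrays, Slfn4 and Sostdc1 each exceeded the highest nonspecific control probe set on 1 of 3. Of the 20, 16 kept their call when each of the 9 arrays was left out in turn, and Camp, Tdrp, Igfbp4 and Tgfbr3 did not. Of all 103 named and called genes of this comparison 70 did so, and Pdcd1, Prdm1, Tbx21, Icos and Cd8a were not among these.

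Genes of type I interferon signalling, the antiviral response, rose together in chronic infection. Of the 30 measured members 25 rose against naive and none fell (28 rose when adjusted over the list alone), with a mean log2 difference of 1.67. Among them Mx1 rose by 3.78 ± 0.27, Usp18 by 2.31 ± 0.15 and Cmpk2 by 2.24 ± 0.16. The list passed the camera test with the preset correlation (adjusted p = 6.22e-20), and had an adjusted p = 0.0982 with an estimated correlation. In the type II interferon list, which holds targets of interferon gamma, 14 of 18 members rose and none fell (16 rose when adjusted over the list alone), with Irgm1 at 1.32 ± 0.11 and Iigp1 at 1.96 ± 0.19. Its mean difference was 1.01 (camera adjusted p = 2.52e-08; adjusted p = 0.24 with an estimated correlation). The means of both lists without the array labelled naive replicate 2 were 1.73 (type I) and 0.82 (type II). With fry and all arrays the adjusted p-values in chronic against naive were 4.3e-05 (type I) and 0.00116 (type II).

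Proliferation genes were higher as well. Of 28 G2/M genes 27 rose and none fell in chronic infection against naive (28 when adjusted over the list alone), among them Cenpe (2.40 ± 0.30), Prc1 (2.26 ± 0.26) and Bub1b (1.90 ± 0.21). The list mean was 1.76 (camera adjusted p = 1.58e-17; adjusted p = 0.436 with an estimated correlation). Of 24 genes of G1/S and DNA replication 22 rose and none fell (23 when adjusted over the list alone), including Ccne2 (1.96 ± 0.22) and Cdc6 (1.93 ± 0.27). Their mean was 1.06 (camera adjusted p = 9.18e-11; adjusted p = 0.471 with an estimated correlation). Of 14 glycolysis genes 8 rose and 1 fell (10 and 1 when adjusted over the list alone), with Tpi1 at 1.01 ± 0.15 and Pgk1 at 0.59 ± 0.09. Their mean was 0.37 (camera adjusted p = 0.000887; adjusted p = 0.491 with an estimated correlation). Ribosomal protein genes were slightly lower: 20 of 36 fell and none rose (25 when adjusted over the list alone), with Rpl12 at -0.34 ± 0.05 and a list mean of -0.16 (camera adjusted p = 7.25e-12; adjusted p = 0.246 with an estimated correlation). Means without the array labelled naive replicate 2 were 1.49 for G2/M, 0.91 for G1/S, 0.29 for glycolysis and -0.15 for ribosomal protein genes.

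The effector regulatory T cell list, which holds genes of activated regulatory T cells, had 13 of 22 members up in chronic infection against naive and none down (17 when adjusted over the list alone). Beside Gzmb and Il10 these included Lgals3 (3.32-fold) and the transcription factor gene Batf (2.47-fold). With the array labelled naive replicate 2 left out, 19 members rose. The list mean was 1.66 with all arrays and 1.07 without the array labelled naive replicate 2 (camera adjusted p = 9.35e-08; adjusted p = 0.531 with an estimated correlation). Of 12 suppressive effector genes 6 rose and none fell (10 when adjusted over the list alone), with Entpd1, which encodes the ectoenzyme CD39, at 2.51 ± 0.47. The list mean was 1.96 (camera adjusted p = 9.29e-05; adjusted p = 0.5 with an estimated correlation). Of 12 inhibitory receptor genes 5 rose and 1 fell (8 and 1 when adjusted over the list alone). Their mean was 1.04 (camera adjusted p = 0.0282; adjusted p = 0.573 with an estimated correlation), and the call was lost without acute replicate 1, acute replicate 2 or chronic replicate 1 (adjusted p = 0.064, 0.0687 and 0.0512). Of 10 transcription factor genes linked to T cell exhaustion 5 rose and none fell (7 when adjusted over the list alone), with Prdm1 at 2.10 ± 0.44 and Nr4a2 at 1.53 ± 0.32. Their mean was 1.07 (camera adjusted p = 0.00169; adjusted p = 0.511 with an estimated correlation). In the Th1 list 7 of 15 members rose and none fell (8 when adjusted over the list alone), among them the chemokine genes Ccl4 (3.61 ± 0.28) and Ccl3 (3.29 ± 0.50), Cxcr3 (1.65 ± 0.26) and Tbx21 (0.90 ± 0.23), which encodes the Th1 regulator T-bet. Its mean was 1.15 (camera adjusted p = 7e-04; adjusted p = 0.511 with an estimated correlation). The CD8 T cell list, also higher in chronic infection, had the same order as the Th1 list on the acute arrays: both were highest on replicate 1, and CD8 genes averaged 8.08 and 8.65 on replicates 2 and 3, where Th1 genes averaged 9.08 and 9.51. Leaving out the array labelled naive replicate 2 gave means of 1.44 for suppressive effectors, 0.70 for inhibitory receptors, 0.76 for exhaustion transcription factors and 1.04 for Th1 genes, with 9, 7, 7 and 8 members up. With fry and all arrays the adjusted p in chronic against naive was 0.0314 for effector regulatory T cell genes and 0.0111 for suppressive effectors. It was 0.0294 for inhibitory receptors, 0.0314 for exhaustion transcription factors and 0.0314 for Th1 genes. The Th1 list did not pass fry without the array labelled naive replicate 2 (adjusted p = 0.0732).

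Resting T cell genes moved the other way. Of 12 measured members 10 fell and 1 rose in chronic infection against naive (11 and 1 when adjusted over the list alone), with Klf3 at -1.04 ± 0.10, Satb1 at -1.19 ± 0.16 and S1pr1, which encodes the receptor for lymphocyte exit from tissues, at -0.90 ± 0.11. The member that rose was Ly6c1 (1.22 ± 0.16). The list mean was -1.22 (camera adjusted p = 7.95e-08; adjusted p = 0.273 with an estimated correlation). The array labelled naive replicate 2 held the highest mean of this list (11.44 against at most 10.87 on the others), and without it the list difference was -1.01. With fry and all arrays the list had an adjusted p = 0.00531.

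Genes that define regulatory T cells depended on that array. Foxp3 differed by 1.90 ± 1.22 between chronic and naive with all arrays (adjusted p = 0.303) and by 0.07 ± 0.10 without it. Ikzf2 differed by 0.92 ± 0.66 (adjusted p = 0.357) and by -0.06 ± 0.12 without it. Il2ra turned its direction, from 1.42 ± 1.29 (adjusted p = 0.472) to -0.50 ± 0.11 (adjusted p = 0.0139). Ctla4 differed by 2.20 ± 0.83 (adjusted p = 0.0941) with all arrays and by 0.98 ± 0.22 (adjusted p = 0.013) without it, and Klrg1 by 2.35 ± 1.03 (adjusted p = 0.142) and 0.80 ± 0.13 (adjusted p = 0.00373). Icos rose by 1.40 ± 0.31 with all arrays and by 0.97 ± 0.13 without this array. The mean of the 15 identity genes differed by 1.15 (camera adjusted p = 0.024; adjusted p = 0.743 with an estimated correlation) and by 0.18 without the array (camera adjusted p = 0.753). With all arrays 3 of the 15 rose and none fell (2 when adjusted over the list alone), and without it 5 rose and 4 fell (the same when adjusted over the list alone). The identity list did not pass fry with all arrays (adjusted p = 0.249).

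Between the arrays of resolved acute infection and the naive ones few single genes were called, which does not show that the groups were alike. Only AA467197 passed the threshold among the 10420 genes, and it was named after its values had been seen. It was higher in acute infection (5.32 ± 0.15 against 3.99 ± 0.11, SD, n = 3 each, limma adjusted p = 0.0364), but 0 of 3 naive and 1 of 3 acute arrays exceeded the highest nonspecific control probe set, so the size of its change was not read. At an unadjusted p under 0.05 there were 1020 genes, where a share of 0.05 of the 10420 genes would be reached with no change at all. With array weights 13 genes passed the adjusted threshold. The call of AA467197 was absent in each fit that left out 1 array other than naive replicate 2, and those fits called 0 genes or, without naive replicate 3, 1 other gene. Without the array labelled naive replicate 2, 6 genes were called: AA467197, Csprs (2.04 ± 0.23), Gzmb (1.02 ± 0.11) and Itgae (1.01 ± 0.11), which encodes the CD103 integrin chain, were higher, and Cntn1 (-1.99 ± 0.24) and 1810046K07Rik lower, the latter with no acute array above that control level. Their adjusted p-values ran from 0.0279 to 0.0327, and all but Csprs, Gzmb and Itgae were named after their values had been seen.

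The genes with the smallest p above the threshold in acute against naive were Csprs (1.87 ± 0.24, adjusted p = 0.126), Oas1g (1.07 ± 0.14), Slpi (2.16 ± 0.31), Clu (1.15 ± 0.17) and Vpreb1 (0.82 ± 0.14) on the higher side, and no array held Vpreb1 above its highest nonspecific control probe set. On the lower side they were Dtx1 (-0.60 ± 0.09, adjusted p = 0.195), the chemokine receptor gene Ccr9 (-1.15 ± 0.18), Igf2bp3 (-1.21 ± 0.20), Ramp1 (-0.71 ± 0.13) and Mfhas1 (-0.51 ± 0.10). Their adjusted p-values reached 0.312. With all 9 arrays Gzmb differed by 1.35 ± 0.24 (adjusted p = 0.27), Il10 by 1.52 ± 0.48, Lag3 by 1.55 ± 0.48, Havcr2 by 1.04 ± 0.25, Pdcd1 by 0.85 ± 0.42 and Icos by 0.87 ± 0.31, with adjusted p-values of these 6 genes between 0.27 and 0.545. The differences without the array labelled naive replicate 2 were 0.98 for Il10, 0.88 for Lag3, 0.80 for Havcr2, 0.27 for Pdcd1 and 0.45 for Icos.

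Within groups and with all arrays, mean correlations were 0.869 for effector regulatory T cell, 0.771 for G2/M and 0.574 for neutrophil genes. Without the array labelled naive replicate 2 they were 0.347, 0.755 and 0.637, so that array carried much of the first value. Camera was preset to 0.01. With fry only heat shock, type II interferon, oxidative phosphorylation, plasma cell and G2/M genes passed in acute against naive (adjusted p from 0.0232 to 0.0454). Effector regulatory T cell and neutrophil genes did not (both 0.196). More gene lists passed camera with that preset, where almost no single gene was called. Markers of other cell types were among them: the largest mean shift was that of neutrophil genes, 1.42 (0.79 without the array labelled naive replicate 2), with none of 10 called, also when adjusted over the list alone (camera adjusted p = 7e-04; adjusted p = 0.511 with an estimated correlation). Plasma cell genes were higher by 0.67 (0.55 without that array), and 2 of 7 rose when adjusted over the list alone, 3 without that array (camera adjusted p = 0.000186; adjusted p = 0.273 with an estimated correlation). CD8 T cell genes, among which Gzmb also stands, were higher by 0.53 (median 0.11; 0.58 without that array), with none of 10 called (1 without that array) and 4 when adjusted over the list alone (camera adjusted p = 0.0305; adjusted p = 0.573 with an estimated correlation). They were higher by 0.23 without acute replicate 1 (adjusted p = 0.46) and by 0.82 without acute replicate 2, and the call was also lost without naive replicate 3 or acute replicate 3 (adjusted p = 0.0607 and 0.0669).

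The 28 G2/M genes were all higher in acute than in naive, by a mean of 0.93 (0.66 without the array labelled naive replicate 2), and 26 rose when adjusted over the list alone although none was called over all genes (camera adjusted p = 2.34e-22; adjusted p = 0.342 with an estimated correlation). Type II interferon genes were higher by a mean of 0.50, 18 of 18 with all arrays, and by 0.31, 16 of 18, without that array, with 3 called when adjusted over the list alone (5 without that array), and Iigp1 had the smallest p (1.05 ± 0.19). This list had a camera adjusted p = 3.08e-07 and an adjusted p = 0.246 with an estimated correlation. Effector regulatory T cell genes were higher by a mean of 0.90, and by 0.31 without that array, with 2 of 22 called when adjusted over the list alone, 7 without that array (camera adjusted p = 1.05e-08; adjusted p = 0.511 with an estimated correlation). The 30 type I interferon genes showed no common shift (mean -0.00023, median 0.012, camera adjusted p = 0.565). Of these, 1 rose and 2 fell when adjusted over the list alone. Identity genes were higher by 1.11 (camera adjusted p = 0.000186; adjusted p = 0.573 with an estimated correlation), and by 0.13 without the array labelled naive replicate 2 (camera adjusted p = 0.451).

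Other lists passed in acute against naive with none of their genes called. Suppressive effectors were higher by 0.89 (3 of 12 when adjusted over the list alone; camera adjusted p = 0.000186; adjusted p = 0.5 with an estimated correlation), and by 0.37 without the array labelled naive replicate 2. G1/S genes were higher by 0.46 (2 of 24 when adjusted over the list alone; camera adjusted p = 5.7e-08; adjusted p = 0.5 with an estimated correlation), and by 0.31 without that array. Ribosomal protein genes were lower by a mean of 0.050 with all arrays (none of 36 when adjusted over the list alone; camera adjusted p = 1.07e-05; adjusted p = 0.436 with an estimated correlation) and by 0.046 without it. Exhaustion transcription factors were higher by 0.51 (2 of 10 when adjusted over the list alone; camera adjusted p = 0.00529; adjusted p = 0.554 with an estimated correlation), a call lost without that array (0.21, adjusted p = 0.064) and without acute replicate 1 (0.39, adjusted p = 0.143). Th1 genes were higher by 0.36 (1 of 15 when adjusted over the list alone; camera adjusted p = 0.042; adjusted p = 0.665 with an estimated correlation). The Th1 call was lost without that array (0.25, adjusted p = 0.251), naive replicate 3 (0.35), acute replicate 1 (0.13), acute replicate 3 (0.37) or chronic replicate 3 (adjusted p = 0.0522), and the mean was 0.59 without acute replicate 2.

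Chronic and acute infection, both at day 16, differed most in type I interferon genes. Ifit3 was 9.10-fold higher in chronic infection (11.23 ± 0.07 against 8.04 ± 0.47, SD, n = 3 each, limma adjusted p = 0.000477), Mx1 7.55-fold, Irf7, an interferon-induced transcription factor gene, 6.42-fold, and Rsad2, which encodes the antiviral enzyme viperin, 6.44-fold. Of the 30 measured members of the list 24 rose and none fell (28 when adjusted over the list alone), with a mean log2 difference of 1.67. The list had a camera adjusted p = 1.01e-30 and an adjusted p = 0.0605 with an estimated correlation. All 3 chronic arrays lay above all 6 naive and acute arrays in the mean of this list.

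**Figure D2:**
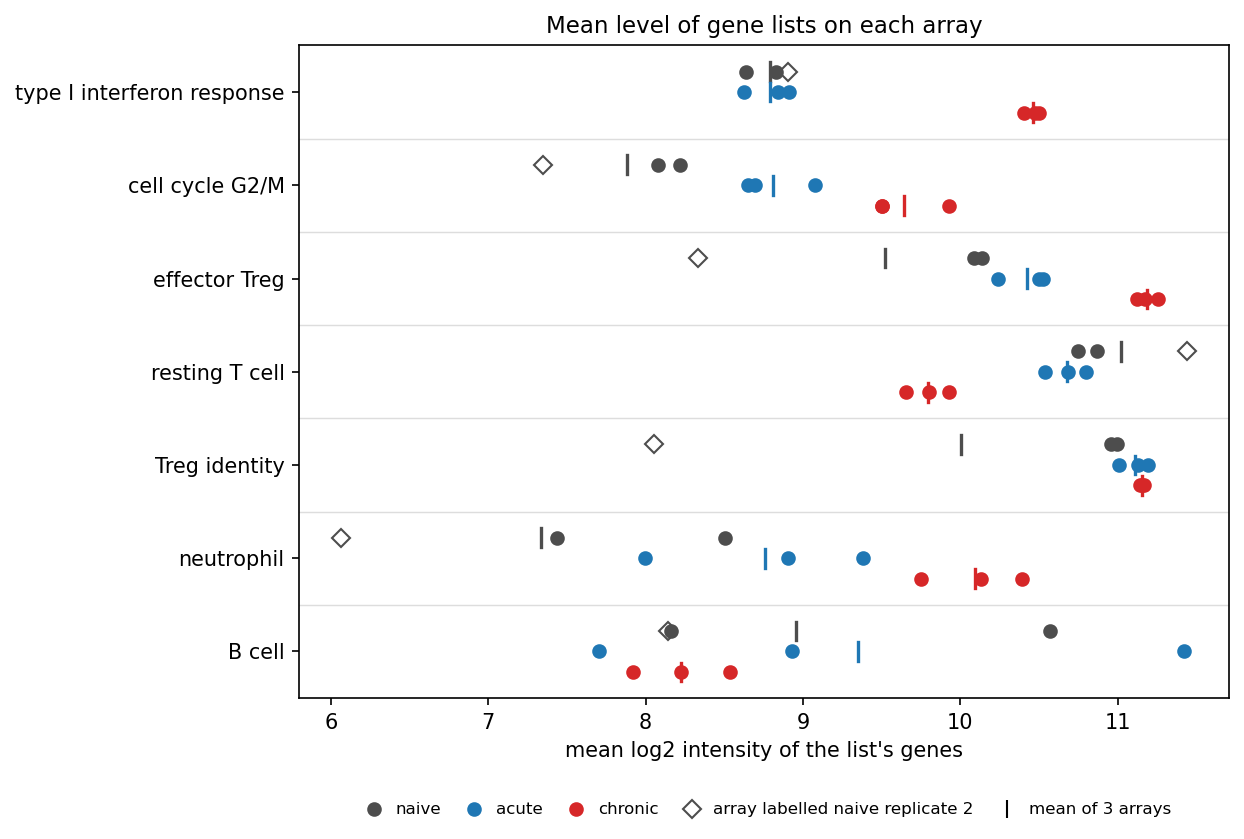
Mean log2 intensity of the measured genes of 7 lists (x axis) on each of the 9 arrays, with a point for each array, a vertical tick for each group mean and an open diamond for the array labelled naive replicate 2. The 3 chronic arrays sit apart in the type I interferon list, 1.67 above the acute mean, while B cell genes range from 7.70 to 11.42 within the acute group.

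In all 524 genes changed between chronic and acute infection, 311 higher and 213 lower in chronic, 146 and 48 of them by at least 2-fold. Without the array labelled naive replicate 2, which enters this comparison only through the shared estimate of the spread, the count was 1410 (797 and 613) and included all 524. The count also moved with the arrays of both groups: it was 915 without acute replicate 1, 173 and 83 without acute replicates 2 and 3, and 119, 131 and 96 without chronic replicates 1, 2 and 3.

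Chosen in the same way, the 10 largest rises in chronic against acute held, beside interferon genes, Sostdc1 (3.42 ± 0.32), Il10 (2.76 ± 0.48), Slfn4 (2.97 ± 0.45) and Ly6i (2.82 ± 0.26), and the others were Oas2 (3.23 ± 0.62), Ifit3 (3.19 ± 0.23), Oasl2 (3.02 ± 0.30), Mx1 (2.92 ± 0.27), Rsad2 (2.69 ± 0.20) and Irf7 (2.68 ± 0.23). The 10 largest falls were Rag1 (-3.43 ± 0.81), Sox4 (-2.76 ± 0.28), Cnn3 (-2.38 ± 0.43), Bach2 (-2.12 ± 0.32), Tmem108 (-2.08 ± 0.38), St8sia6 (-1.96 ± 0.16), Foxp1 (-1.83 ± 0.32), Il6ra (-1.79 ± 0.35), Aqp3 (-1.77 ± 0.25) and Ttc28 (-1.74 ± 0.31). Adjusted p-values of these 20 genes ran up to 0.0469, for Rag1. No acute array held Ly6i above its highest nonspecific control probe set, and 1 of 3 did for Sostdc1, so the sizes of these rises are approximate. Rag1, a recombinase gene of developing lymphocytes, stood at 9.15 on acute replicate 2 and 5.55 on acute replicate 1, and no chronic array exceeded its highest nonspecific control probe set. Among the acute arrays the B cell list mean was likewise highest on replicate 2 and lowest on replicate 1 (11.42 and 7.70). Bach2 (11.65 and 10.09), Foxp1 (11.84 and 10.40), Sox4, Cnn3 and Tmem108 had the same order on the acute arrays. The other falls, St8sia6, Il6ra, Aqp3 and Ttc28, were highest on acute replicate 3. Which cells these falls came from was not settled. Of the 20 genes 9 kept their call when each array was left out in turn: Ifit3, Irf7, Ly6i, Mx1, Oasl2, Rsad2, Sostdc1, Sox4 and St8sia6. Of all 64 named and called genes of this comparison 18 did so, among them Gzmb, Havcr2, Il21, Ccl4, Irgm1 and Klf3.

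Some effector genes were higher in chronic than in acute infection, among them 4 of the 22 on the effector list (camera adjusted p = 0.000155; adjusted p = 0.624 with an estimated correlation). Gzmb rose 5.09-fold (adjusted p = 0.00174), Havcr2 3.88-fold (adjusted p = 0.00513) and Il21, a cytokine gene of follicular helper T cells, 5.54-fold (adjusted p = 0.000867). Tbx21 rose by 1.04 ± 0.23 and Batf by 0.75 ± 0.17. Lag3 differed by 1.72 ± 0.48 (adjusted p = 0.0768), Pdcd1 by 0.89 ± 0.42 (adjusted p = 0.246) and Icos by 0.53 ± 0.31 (adjusted p = 0.347), and all 3 passed without the array labelled naive replicate 2 (adjusted p = 0.000558, 0.00882 and 0.0221). Foxp3 differed by 0.33 ± 1.22 (adjusted p = 0.901) with all arrays and by 0.33 ± 0.09 without that array (adjusted p = 0.0409). Il2ra differed by -0.41 ± 1.29 (adjusted p = 0.881) and by -0.41 ± 0.10 without it (adjusted p = 0.0304). The difference between both fits lies in the spread, since that array belongs to neither group.

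**Figure D3:**
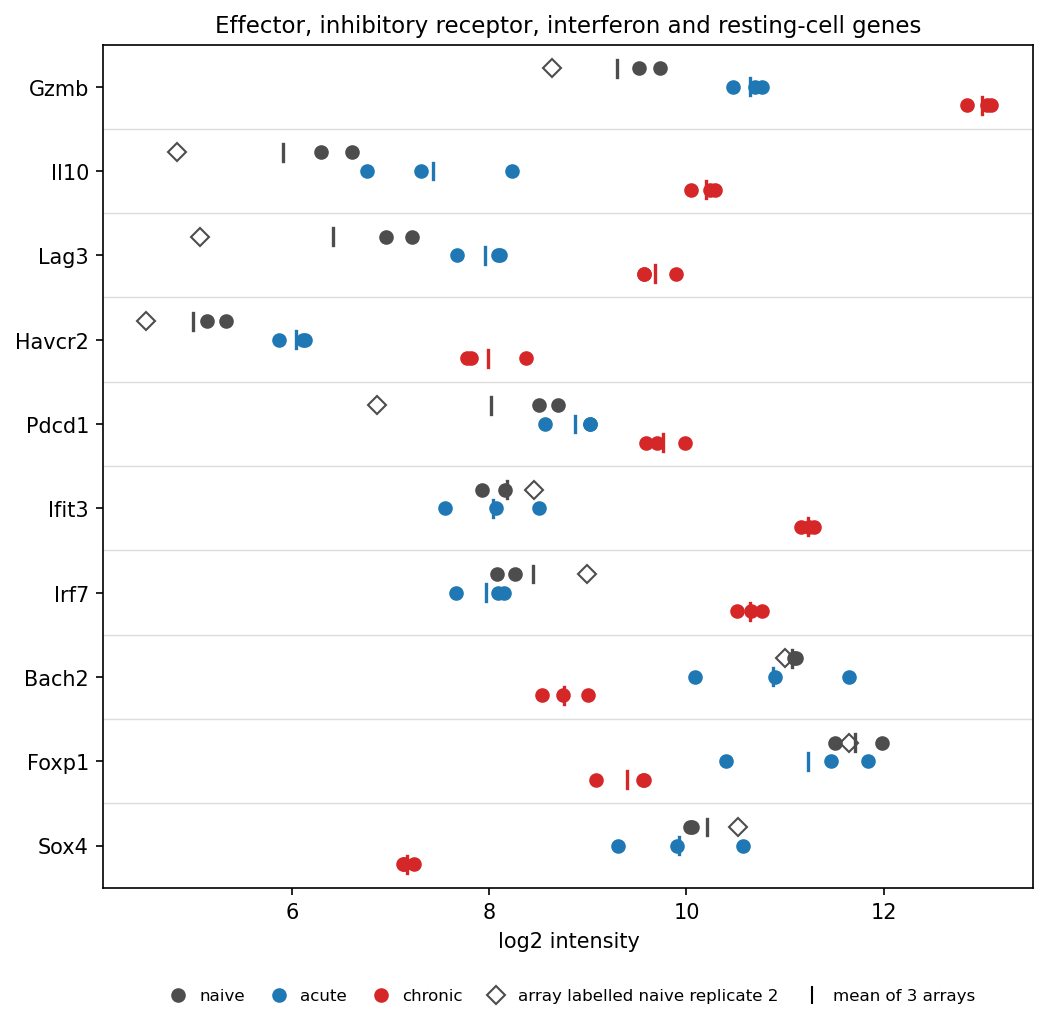
Log2 intensity (x axis) of 10 genes on each of the 9 arrays, with a point for each array, a vertical tick for each group mean and an open diamond for the array labelled naive replicate 2. In chronic infection Gzmb averaged 12.99 against 10.64 in acute and Ifit3 11.23 against 8.04, while Sox4 averaged 7.17 against 9.92.

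Among the lists, effector regulatory T cell genes were higher in chronic than in acute infection by a mean of 0.76 (4 of 22 rose, none fell, 6 when adjusted over the list alone; camera adjusted p = 0.000155; adjusted p = 0.624 with an estimated correlation). Without the array labelled naive replicate 2, 18 of the 22 rose. G2/M genes were higher by 0.84 (3 of 28 rose, none fell, 25 when adjusted over the list alone; camera adjusted p = 1.61e-11; adjusted p = 0.5 with an estimated correlation), and without that array 27 rose. The Cenpa call in this list rested on the probe set with the highest signal, since another probe set of the gene differed by -0.98. G1/S genes were higher by 0.60, with 1 of 24 called and 18 when adjusted over the list alone (camera adjusted p = 1.58e-08; adjusted p = 0.5 with an estimated correlation), and without that array 15 were called and 22 when adjusted over the list alone. Resting T cell genes were lower by a mean of 0.88: 7 of 12 fell and 1 rose (10 and 1 when adjusted over the list alone), with Klf3 at -0.95 ± 0.10 and Klf2 at -0.62 ± 0.10. That list had a camera adjusted p = 6.67e-08 and an adjusted p = 0.273 with an estimated correlation, and without that array 10 fell and 1 rose. The 15 identity genes differed by a mean of 0.044 (camera adjusted p = 0.939), and none was called, also when adjusted over the list alone, while without the array labelled naive replicate 2, 4 rose and 2 fell (the same counts when adjusted over the list alone).

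Type II interferon genes were higher in chronic than in acute infection by 0.51 (6 of 18 rose, none fell, 11 when adjusted over the list alone), with Irgm1 at 1.07 ± 0.11. The list had a camera adjusted p = 1.35e-06 and an adjusted p = 0.246 with an estimated correlation. Suppressive effectors were higher by 1.07 (2 of 12 rose, 3 when adjusted over the list alone; camera adjusted p = 0.000977; adjusted p = 0.511 with an estimated correlation), and inhibitory receptors by 0.63 (2 of 12 rose, 5 when adjusted over the list alone; camera adjusted p = 0.0102; adjusted p = 0.531 with an estimated correlation). Th1 genes were higher by 0.79 (4 of 15 rose, 7 when adjusted over the list alone), with Ccl4 at 2.14 ± 0.28 and Nkg7 at 1.25 ± 0.21. The Th1 list had a camera adjusted p = 0.000823 and an adjusted p = 0.511 with an estimated correlation. Glycolysis genes were higher by 0.30 (5 of 14 rose, 9 when adjusted over the list alone), with Aldoa at 0.36 ± 0.06 (camera adjusted p = 0.000111; adjusted p = 0.436 with an estimated correlation). Ribosomal protein genes were lower by a mean of 0.11 (3 of 36 fell, 14 when adjusted over the list alone), with Rps19 at -0.29 ± 0.05 (camera adjusted p = 2.93e-10; adjusted p = 0.273 with an estimated correlation). Exhaustion transcription factors were higher by 0.56 (1 of 10 rose, 2 when adjusted over the list alone; camera adjusted p = 0.0245; adjusted p = 0.619 with an estimated correlation), a call lost without acute replicate 2 (0.46, adjusted p = 0.0687) or chronic replicate 1 (0.54, adjusted p = 0.0624).

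These numbers of called genes depended on the spread that the array labelled naive replicate 2 added, although it belongs to neither group. Without it the list means stayed the same, and more members rose: 12 of 18 type II interferon genes (13 when adjusted over the list alone), 8 of 12 suppressive effectors (10), 7 of 12 inhibitory receptors (7), 6 of 15 Th1 genes (7) and 5 of 10 exhaustion transcription factors (6). Of the glycolysis genes 8 rose and 1 fell (10 and 1), and 7 of 36 ribosomal protein genes fell (14).

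The responses to acute and chronic infection were set against each other over all tested genes. Their log2 differences against naive had a covariance of 0.143, and unchanged groups sharing the naive arrays gave 0.0616 on average over 100 simulations, a difference of 0.0814. Without the array labelled naive replicate 2 the covariance was 0.114 against a simulated 0.0376, a difference of 0.0765. The correlation across genes, which are not independent replicates, was 0.721 against a simulated 0.734 with all arrays, and 0.704 against 0.631 without that array. The single gene called in acute infection, AA467197, was also called in chronic infection (0.13 expected of independent lists, 2.68 called in both on average in the simulation). Without that array 4 genes rose in both (0.6 expected) and 2 fell in both (0.189 expected), where the simulation called 0.39 in both on average. With all arrays the simulated correlations reached 0.764, above the observed one. The simulated groups were all unchanged, whereas 2184 genes changed in chronic against naive, which widens the spread that a correlation divides by. The correlation with all arrays therefore cannot decide on likeness beyond the shared naive arrays, and the covariance lay above its simulated mean. Without the array labelled naive replicate 2 the observed correlation lay above the highest simulated one (0.672), in a simulation that treated genes as independent. The naive arrays were too few to split, so part of the remaining likeness may still come from sharing them.

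Markers of other cell types differed between arrays. Neutrophil genes had a list mean of 7.34 ± 1.22 in naive, 8.76 ± 0.70 in acute and 10.09 ± 0.32 in chronic infection (SD, n = 3 each). Of its 10 measured members 5 rose in chronic against naive and none fell (7 when adjusted over the list alone), by a mean of 2.75 (2.12 without the array labelled naive replicate 2; camera adjusted p = 0.000721; adjusted p = 0.511 with an estimated correlation). Monocyte and macrophage genes were higher by 0.87 in chronic than in naive (4 of 21 rose, also 4 when adjusted over the list alone; camera adjusted p = 0.0177; adjusted p = 0.747 with an estimated correlation), by 0.36 without the array labelled naive replicate 2 (camera adjusted p = 0.525) and by 1.38 without naive replicate 3. That call was also lost without chronic replicate 1 (0.76, adjusted p = 0.0633). The members Fcgr1 and Itgam rose from a level at which 1 of 3 naive arrays exceeded the highest nonspecific control probe set. CD8 T cell genes were higher by 1.14 (3 of 10 rose, 4 when adjusted over the list alone; camera adjusted p = 0.0239; adjusted p = 0.568 with an estimated correlation), and Cd8a rose by 1.93 ± 0.43. Plasma cell genes, which include Xbp1 (1.03 ± 0.14) and Prdm1 that regulatory T cells also use, were higher by 1.34 (4 of 7 rose, 7 when adjusted over the list alone; camera adjusted p = 0.000568; adjusted p = 0.273 with an estimated correlation). With the array labelled naive replicate 2 left out the means were 1.20 for CD8 T cell and 1.23 for plasma cell genes.

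In chronic against acute infection, neutrophil genes were higher by 1.33 (none of 10 called, 1 when adjusted over the list alone; camera adjusted p = 0.0151; adjusted p = 0.606 with an estimated correlation). In the fit without the array labelled naive replicate 2, which belongs to neither group, 5 of the 10 rose (6 when adjusted over the list alone). The list's call was lost without acute replicate 1 (0.95, adjusted p = 0.275) or chronic replicate 2 (1.18, adjusted p = 0.0526). Monocyte and macrophage genes were higher by 0.60 (3 of 21 rose, 5 when adjusted over the list alone; camera adjusted p = 0.0138; adjusted p = 0.743 with an estimated correlation), and by 0.19 without acute replicate 1 (adjusted p = 0.564). Its call was lost without chronic replicate 1 as well (0.48, adjusted p = 0.065). Plasma cell genes were higher by 0.68 (2 of 7 rose, 3 when adjusted over the list alone; camera adjusted p = 0.0156; adjusted p = 0.491 with an estimated correlation). Leaving out the array labelled naive replicate 2 gave 5 of 21 monocyte and macrophage and 3 of 7 plasma cell genes up (5 and 4 when adjusted over the list alone). CD8 T cell and NK cell genes were each higher by 0.61 and did not pass (camera adjusted p = 0.0764 and 0.0619). The CD8 T cell list passed without acute replicate 1 (0.92, adjusted p = 0.0151), acute replicate 3 or chronic replicate 2. The NK cell list passed without acute replicate 1 (0.86, adjusted p = 0.021), acute replicate 3, chronic replicate 3 or the array labelled naive replicate 2.

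B cell genes varied inside groups more than between them. Their list mean was 11.42 on acute replicate 2 and 10.57 on naive replicate 3, and between 7.70 and 8.93 on the other 7 arrays. No B cell gene was called in chronic against acute, also when adjusted over the list alone, with a list mean of -1.12 (camera adjusted p = 0.01; adjusted p = 0.743 with an estimated correlation). Acute replicate 2 carried this difference: without it the mean was -0.09 (adjusted p = 0.868), and without acute replicate 1 it was -1.95. In acute against naive the B cell list differed by 0.39 (camera adjusted p = 0.678), by -0.01 without the array labelled naive replicate 2, by -0.64 without acute replicate 2, by 1.22 without acute replicate 1 and by 1.20 without naive replicate 3. The last 3 of these passed the list test (adjusted p = 0.000944, 0.000245 and 0.00273), in opposite directions, so no direction is given for this list.

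Signal ratios that read RNA integrity overlapped between the groups. The 3' over 5' signal of Actb was 1.28 ± 0.04 in naive, 1.25 ± 0.06 in acute and 1.31 ± 0.11 in chronic (SD, n = 3 each). The smallest p that an exact permutation test of 3 against 3 arrays allows is 0.1, and the two-sided exact p-values for Actb were 0.4, 0.8 and 0.6 for acute against naive, chronic against naive and chronic against acute. For Gapdh they were 0.3, 0.8 and 0.5. Other quality values had no overlap between a pair of groups, at the smallest exact permutation p of 0.1: the highest nonspecific control probe set was 5.26 to 5.44 on acute and 4.51 to 4.91 on chronic arrays, the trimmed mean was higher on each acute than on each naive array, and poly-A controls were higher on each chronic than on each naive array. The first principal component of the tested genes took 47.9% of the variance and placed the 3 chronic arrays between 31.2 and 39.1, the acute arrays between -9.59 and 3.61, and the array labelled naive replicate 2 at -46.6, farther out than the other naive arrays (-23.4 and -18.1).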

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

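The tests of RNA quality, T cell markers and the resting list on 1 array, the covariates and the correlation of neutrophil genes were chosen after the result was seen. So was the use of quantile normalization as a test of the scaling behind the interferon difference. The comparison of chronic with acute, the list tests, quantile normalization as a setting and the splits of the samples were planned.

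The array labelled naive replicate 2 was low in Foxp3 (5.23 against at least 10.37 on the other 8 arrays). Degraded RNA is argued against by the 3' over 5' signals of Actb, 1.27 on this array and up to 1.43 on the others, and of Gapdh (1.18 and up to 1.27), and dilution by cells that are not T cells by the T cell markers, whose median lay 0.107 above the other 8 arrays where Foxp3 lay 5.41 below (difference -5.41). The array stood apart in other controls, with the lowest 18S rRNA (7.67 against at least 9.84) and poly-A signals (7.62 against at least 8.07), so a technical difference in its preparation stays open. The resting T cell list lay 0.572 above the highest other array, which is consistent with CD4 T cells that lack the CD25-positive cells, from a failed isolation step or a wrong label. No biological explanation was tested, and a wrong label stays open beside a failed isolation.

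Type I interferon genes were higher in chronic than in acute infection by a list mean of 1.67 (adjusted p = 0.0605 with an estimated correlation). With the neutrophil list mean as a covariate over 9 arrays the difference was 1.72 ± 0.132 (SE), and with the monocyte and macrophage list mean it was 1.72 ± 0.103. Such a fit takes its slope from the scatter within groups. It therefore cannot decide whether cells of either type carried interferon transcripts on the chronic arrays only, and both cell types stay open as a source. After quantile normalization the difference was 1.72, which argues against the scaling of the arrays. The state of infection may underlie the difference and stays a hypothesis, since strain of virus, route of injection and persistence differed together between the groups.

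Neutrophil genes were higher in chronic than in naive by a list mean of 2.75 (camera adjusted p = 0.000721; adjusted p = 0.511 with an estimated correlation). Within groups, and without the array labelled naive replicate 2, the list's 10 genes had a mean correlation of 0.637, against 0.25 at the 95th percentile of 1000 random lists. The G2/M and Th1 lists exceeded that level too (0.755 and 0.682). The correlation therefore cannot tell neutrophil RNA carried over in varying amounts from genes regulated together. The genes with the highest probe set signal, which does not rank transcripts across genes, averaged 10.41, 11.93 and 13.06 (S100a9), 9.06, 11.52 and 12.91 (Ngp) and 10.08, 11.62 and 12.66 (S100a8) in naive, acute and chronic arrays. The magnetic isolation of CD4+CD25+ cells would remove neutrophils if complete, and 0 of the 10 genes stand on another list. Expression of these genes in the T cells themselves was not tested and stays open.

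Several results differed between chronic and acute infection, tested as chronic minus acute by limma for genes and by camera for lists, and had estimates of opposite sign against naive. Higher in chronic were Ifit3 (3.19), Oas2 (3.23), Oasl2 (3.02), Ly6i (2.82), Irf7 (2.68), Tbx21 (1.04) and the type I interferon list (1.67, adjusted p = 1.01e-30; adjusted p = 0.0605 with an estimated correlation). Lower in chronic were Rag1 (-3.43), Aqp3 (-1.77), Clu (-1.24), Vpreb1 (-0.87) and the B cell list (-1.12, adjusted p = 0.01; adjusted p = 0.743 with an estimated correlation). None of these genes and lists passed its test in acute against naive with all arrays, so opposite directions are not shown. Without the array labelled naive replicate 2 the acute estimates moved from -0.13 to 0.76 for Oas2, the sign of chronic infection, from -0.48 to -0.20 for Irf7, from -0.32 to -0.15 for Oasl2 and from -0.00023 to 0.06 for the type I interferon list, those of Tbx21 (-0.06) and Aqp3 (0.09) lay near 0, and in chronic infection Clu (-0.09) and Vpreb1 (-0.04) lay near 0 with all arrays. Acute replicate 2 carried the B cell list: without it the chronic minus acute difference was -0.09 (adjusted p = 0.868), and acute against naive went from 0.39 to -0.64. No chronic array held Rag1, no acute array Ly6i and no array at all Vpreb1 above its highest nonspecific control probe set, so these sizes are approximate. The poly-A control probe sets, which read RNA added during labelling and lie outside the gene comparisons, were 2.23 higher in chronic than in naive, with every chronic array above every naive one (exact permutation p = 0.1, the smallest 3 against 3 arrays allow).

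The 10 splits of 6 arrays into 3 and 3 are too few for a share under 0.05. In chronic against naive the real split called 2184 genes and the highest other 0 (1 split in 10 as large), and in chronic against acute 524 and 0 (1 split in 10). In acute against naive 2 of the splits gave at least the real 1 gene, and the highest other called 20. That split set naive replicates 1 and 2 with acute replicate 1 against naive replicate 3 with acute replicates 2 and 3. The B cell list mean separated these sides, at 8.16, 8.14 and 7.70 against 10.57, 11.42 and 8.93. So did the monocyte and macrophage list mean, at 7.45, 6.40 and 6.88 against 8.43, 8.12 and 8.10. Whether RNA of these cell types accounts for the 20 genes was not tested.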

How the results depend on the processing

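The B cell covariate, and the list tests without the array labelled naive replicate 2, were chosen after the data had been seen. In acute against naive, 1 gene was called and 0 with no filter, a stricter filter, quantile normalization, equal medians, an offset of 32, only the 6 arrays compared, the replicate block or the B cell covariate (1020 genes at an unadjusted p under 0.05 with limma as reported). It was 13 with array weights, 7 with every probe set tested, 74 without naive replicate 2 and with the B cell covariate, and 0 to 6 with 1 array left out. Genes shared by both responses numbered 1, and 0 under the same 8 settings, 12 with array weights, 68 without naive replicate 2 and with the B cell covariate, and 0 to 6 with 1 array left out. In chronic against naive, 2184 genes became 3908 with array weights, 752 with a 2-fold threshold, 3465 with every probe set and 999 to 2548 with 1 array left out. In chronic against acute, 524 genes became 2991 with array weights, 1204 with the 6 arrays alone, 239 with the replicate block (232 shared), 194 with a 2-fold threshold, 1533 without naive replicate 2 and with the B cell covariate, and 83 to 1410 with 1 array left out. Of 96 list tests 52 passed, 0 with an estimated correlation, 27 with fry, and without naive replicate 2 these were 0 and 32 (47 to 56 with 1 array left out). Directions reversed for Cenpa in chronic against acute with the mean of its probe sets (-0.19), Il2ra in chronic against naive without naive replicate 2 (-0.50, and -0.55 with the B cell covariate as well), the Th17 list (-0.39 and -0.39) and the monocyte and macrophage list (-0.24 and -0.23) in acute against naive in the same settings, and the B cell list in acute against naive without acute replicate 2 (-0.64). With 1 array left out the highest values were 2.46 (Il2ra, chronic against naive), 0.87 (Th17), 0.78 (monocyte and macrophage) and 1.22 (B cell). The B cell list has no value with its own mean as covariate. Fewer genes passed a 2-fold threshold by construction, and for the other settings the cause was not tested. The median of all genes in chronic against acute was 0.04 as deposited and 0.10 after quantile normalization. Fits with 1 array left out keep 2 arrays in a group, and the highest nonspecific control probe set on each array (4.37 to 5.47) limits what can be read of dim genes.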

Other observations

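The follicular T cell list held members with large rises in chronic infection. Most naive arrays did not hold Sostdc1 above their highest nonspecific control probe set, so the size of its rise is approximate. Sostdc1 rose by 4.17 ± 0.32 and Il21 by 2.64 ± 0.22 against naive, and the list mean was 0.78 (median 0.33, camera adjusted p = 0.0991, 10 of 12 positive, 3 of 12 rose, also 3 when adjusted over the list alone). It was 0.61 (median 0.08, 2 of 12 rose) without the array labelled naive replicate 2, and the list passed its test without naive replicate 1 (0.84, adjusted p = 0.0496) or naive replicate 3 (0.91, adjusted p = 0.0325). Against acute it was 0.54 (median 0.09, camera adjusted p = 0.27). Cytokines of conventional CD4 T cells included Ifng, which rose by 2.22 ± 0.57 in chronic against naive (adjusted p = 0.0245). That list's mean was 0.85 (camera adjusted p = 0.297), and in acute against naive its mean was 0.03 while the test pointed down (camera adjusted p = 0.792), and -0.37 without acute replicate 1 (adjusted p = 0.0295).

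Immediate early and receptor-induced genes were higher by 0.46 in acute against naive (none of 18 called, also when adjusted over the list alone, where 4 rose without the array labelled naive replicate 2; camera adjusted p = 0.0063; adjusted p = 0.566 with an estimated correlation), and by 0.13 without acute replicate 1 (adjusted p = 0.396). In chronic against naive they were higher by 0.88, with 5 of 18 called (5 when adjusted over the list alone; 10 without that array, 10 up and 1 down when adjusted over the list alone; camera adjusted p = 0.0196; adjusted p = 0.606 with an estimated correlation), among them Egr2 (0.95 ± 0.19) and Dusp1 (1.62 ± 0.45), and the list's call was lost without chronic replicate 1 (0.81, adjusted p = 0.0703). Heat shock genes were higher by 0.45 in acute against naive (none of 8 called, 3 when adjusted over the list alone and 5 without that array; camera adjusted p = 0.00408; adjusted p = 0.273 with an estimated correlation) and by 0.25 without naive replicate 1, and Dnaja1 fell by 0.42 and Dnajb1 by 0.55 on the log2 scale in chronic against acute, where the list mean was -0.12 (camera adjusted p = 0.297).

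Oxidative phosphorylation genes were lower by small amounts, -0.07 in acute (camera adjusted p = 0.000111; adjusted p = 0.24 with an estimated correlation) and -0.05 in chronic infection against naive (camera adjusted p = 0.0497; adjusted p = 0.491 with an estimated correlation), with 4 of 37 called in chronic and 1 when adjusted over the list alone (2 and 0 without the array labelled naive replicate 2). The chronic call was lost in 7 of the 9 fits with 1 array left out (adjusted p up to 0.0756). Cholesterol synthesis genes were lower by a mean of 0.17 in acute against naive (mean -0.17; none of 16 called, 1 fell when adjusted over the list alone; camera adjusted p = 0.00678; adjusted p = 0.573 with an estimated correlation), where single arrays moved the list mean between -0.28 (without acute replicate 1) and -0.08 (without acute replicate 2, adjusted p = 0.283), it was -0.26 without naive replicate 1, and the call was also lost without naive replicate 3 (adjusted p = 0.0732). Of its members Lss fell in chronic against naive to a level at which 1 of 3 chronic arrays exceeded the highest nonspecific control probe set. Resting T cell genes differed by -0.34 in acute against naive (none of 12 called, also when adjusted over the list alone; camera adjusted p = 0.00147; adjusted p = 0.5 with an estimated correlation), by -0.13 without the array labelled naive replicate 2, and the call was lost without acute replicate 1 (-0.28, adjusted p = 0.0608).

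Chemokine receptor and adhesion genes went both ways in chronic against naive, with 3 of 22 up and 3 down (4 and 3 when adjusted over the list alone). Ccr8 rose by 2.00 ± 0.33 and Ccr9 fell by 2.07 on the log2 scale, and the list mean was 0.17 while the test pointed down (camera adjusted p = 0.939), and -0.14 without the array labelled naive replicate 2 (4 up and 5 down, the same when adjusted over the list alone). Th2 genes had a mean of 0.30 in chronic (camera adjusted p = 0.939) and 0.08 in acute against naive, where the test pointed down (camera adjusted p = 0.939). Th17 genes differed by -0.11 in chronic against naive (camera adjusted p = 0.766) and by -0.91 without the array labelled naive replicate 2 (camera adjusted p = 0.0238; adjusted p = 0.305 with an estimated correlation). Costimulatory and TNF receptor genes were higher by 0.87 in chronic against naive (camera adjusted p = 0.274), where 3 of 8 rose and 1 fell (4 and 1 when adjusted over the list alone), and Tnfrsf18, which encodes GITR, rose by 0.96 ± 0.30. Without that array the list mean was 0.41 (camera adjusted p = 0.0239; adjusted p = 0.471 with an estimated correlation), 5 rose and 0 fell (5 and 1 when adjusted over the list alone), and Tnfrsf18 rose by 0.53.

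Among other cell types, NK cell genes differed by 0.38 in chronic against naive (camera adjusted p = 0.758), with Gzmb up and Klra8 down to a level at which no chronic array exceeded the highest nonspecific control probe set. Dendritic cell genes had a mean of -0.12 and a median of 0.24 with a test that pointed up (camera adjusted p = 0.939), red cell and megakaryocyte genes a mean of 0.05 with a test that pointed down (camera adjusted p = 0.766), and stroma and endothelium genes a mean of -0.03 and a median of 0.05 (camera adjusted p = 0.939).

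Leaving out the array labelled naive replicate 2 gave means of 0.70 and 1.11 for immediate early genes in acute and chronic infection against naive, and -0.05 and -0.03 for oxidative phosphorylation genes. In acute against naive it gave 0.62 for heat shock and -0.09 for cholesterol synthesis genes. On that array 764 genes lay more than 1 log2 unit below and 343 more than 1 above the mean of the other 8 arrays. Replicate numbers did not pair the arrays: in 0 of 9 cases was the residual of an array best correlated with the array of its own number in the other group, where the correlations ran from -0.268 to 0.162.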
